A study of Homo sapiens with 20 samples.

How the data were processed

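Stranded mRNA libraries (TruSeq) of SUM159PT cells were sequenced from 20 samples in 7 groups, with tumorspheres grown through 2 rounds of 6 days. The deposited table holds read counts per Entrez gene for each library, made by the authors with STAR and hg38 per the labels, which do not state the counting tool, its strand setting or the annotation. A column of gene length in bases, per the file headers used in the counting, was deposited beside the counts. It was not used in the check of length trends, which took length and GC content from the longest GENCODE transcript of each gene. The counts are whole numbers with no normalization. Of 27864 Entrez IDs, 27740 were matched to gene symbols and coordinates. All 20 libraries were used, and each was taken as a replicate of its group. The labels do not state that replicates were separate cultures, so p-values measure the spread between these libraries.

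Genes were filtered with filterByExpr in edgeR 4.0.16 (R 4.3.3), which left 16323, and library sizes were scaled by TMM. A quasi-likelihood negative binomial model with 1 coefficient per group was fitted to all libraries, with 13 residual degrees of freedom and a biological coefficient of variation of 0.143. Contrasts covered 3D against 2D in wt, labelled KOs and KOd, each pool and the mean of the pools against wt in 2D and in 3D, the interaction of pool and culture, KOd against labelled KOs, and tumorsphere medium against 2D and 3D in wt. Adjusted p (Benjamini-Hochberg) under 0.05 counted as passed, and genes changed in both pools had to pass in each in the same direction. Log2 fold changes are given with the SE of the model, and log2 CPM used a prior count of 2. For 46 gene lists, of which those with fewer than 5 tested members were not tested, camera in limma 3.58.1 was run on voom weights with a preset correlation of 0.01 and again with an estimated one.

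The groups, contrasts, gene lists, thresholds and rule for named genes were set before the data were examined, as were the alternatives except 3, named with their effect in the closing section. Named genes were NNMT and tested genes near NNMT, the 8 largest rises and the 8 largest falls per contrast among genes with a mean log2 CPM of at least 2 and no overlap between replicates, and up to 4 members of each list with the smallest adjusted p. For the pools against wt the ranking took the smaller change of the 2 pools, and for the interaction the same sign in both pools was required. Against wt most genes of these rules for the mean of the pools are given for each pool, interactions are given for the mean of the pools, and genes without a symbol were left out. Among the genes named as nearly absent in both pools, BEX1 and KLF8 were chosen after their values were seen. The alternatives were RLE factors, library totals alone, no filter, a strict filter (1 CPM in at least 3 libraries), DESeq2 1.42.0, limma-voom, the compared groups alone, the replicate letter as a block in all groups and in wt 3D and KOd 3D alone, adjusted p under 0.01, an absolute log2 fold change of at least 1, fry in place of camera, leaving out 1 library at a time, leaving out ribosomal RNA genes, and leaving out 3 libraries that stand apart. Replicate letters do not pair libraries across groups in the labels, so no pairing was used in the model. In the data, deviations from the group means correlated over 0.1 in every same-letter pair only for wt 3D and KOd 3D (r = 0.210, 0.218 and 0.342), where replicate C stood apart in both groups and unlike letters A and B correlated too (0.125 and 0.208), so a block within these 2 groups was added. Correlations between changes that share control libraries were compared with simulated groups without change.

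The pipeline was tested on simulated data of the same depth with 14588 genes, in which 38% of changes of 0.5 on the log2 scale, 86% of 1 and 96% of 2 were recovered for wt 3D against 2D, with 5.88% false calls. For the mean of the pools in 2D it recovered 48%, 92% and 100%, with 6.11% false calls, and for the interaction 63.5% of changes of 1, with 4.51%. Changes were put into 50 genes per size, and 200 for the interaction. These are far fewer than passed in the measured data, so the rates need not hold there. Some results are not reported here. Protein, DNA, splicing and sequence variants were not analysed here.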

Results

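mRNA was sequenced from SUM159PT, a triple-negative breast cancer cell line, grown as adherent cells (2D) or as secondary tumorspheres in suspension (3D). Wild-type cells (wt) were compared with 2 oligoclonal pools made to lack NNMT, the cytosolic enzyme that methylates nicotinamide with S-adenosylmethionine. The KOs pool carried 1 sgRNA at the transcription start site, and the KOd pool carried 2 sgRNAs that delete exon 1. The 20 libraries formed 7 groups: wt, KOs and KOd in 2D and in 3D with n = 3 each, and adherent wt cells moved to tumorsphere medium with n = 2. Read totals lay between 26396964 and 43744817, and the libraries labelled KOs had 37316513 to 43744817. Ribosomal RNA took 0.926% to 2.70% of the counts in the libraries labelled KOs and 2.82% to 8.46% in the others. The other libraries had at most 32016875 reads, so both traits set all libraries labelled KOs apart. A difference in how these libraries were made was not tested and cannot be told apart from the pool where they are compared. In 3 groups 1 library stood apart from its replicates: labelled KOs 2D replicate A, wt 3D replicate C and KOd 3D replicate C.

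NNMT (Entrez 4837, chromosome 11, 114257806 to 114313536) was measured at 117 ± 13.3 CPM (TMM-scaled, mean ± SD, n = 3) in wt 2D and 98.4 ± 27.5 in wt 3D. In KOd it was 4.55 ± 0.139 CPM in 2D and 5.15 ± 0.497 in 3D, a log2 fold change (± SE) against wt of -4.68 ± 0.21 and -4.26 ± 0.20 (adjusted p = 3.7e-11 and 7.1e-11). In the libraries labelled KOs it was 106 ± 27.6 CPM in 2D and 84.8 ± 1.75 in 3D, and the log2 fold changes of -0.14 ± 0.17 and -0.21 ± 0.17 did not pass the test (adjusted p = 0.52 and 0.30). Without the 3 libraries that stand apart these NNMT changes were -0.31, which passed, in 2D and 0.05 in 3D, and their sign rested on 1 library each, with 0.05 in 2D without labelled KOs 2D replicate C and 0.02 in 3D without wt 3D replicate C. Whether an sgRNA at the transcription start site lowers the mRNA, or the protein alone, is not shown here, and the protein was not analysed. The NNMT mRNA thus gives no evidence of a knockout in the libraries labelled KOs, and it does not check the KOs label. NNMT rose in adherent wt cells in tumorsphere medium, with 236 ± 14.6 CPM (n = 2) and a log2 fold change of 1.01 ± 0.19 (adjusted p = 5.2e-04).

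**Figure D1:**
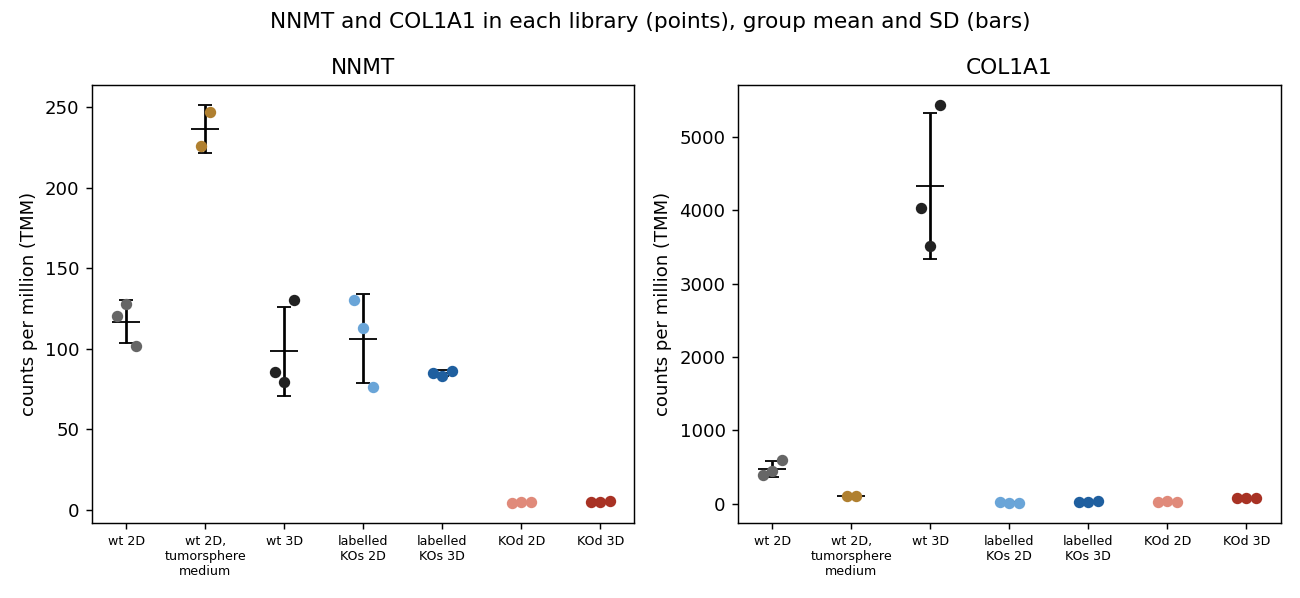
CPM (TMM scaling, linear axes) of NNMT and COL1A1 in each library, shown as points, with the group mean and SD as bars (n = 3, or n = 2 for tumorsphere medium). NNMT lay between 4.39 and 5.64 CPM in the KOd libraries and between 76 and 130 in those labelled KOs, and COL1A1 averaged 4330 CPM in wt 3D.

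The first comparison asks what tumorsphere culture changes in wt cells. Genes of the extracellular matrix were far higher in tumorspheres: log2 fold changes were 9.94 ± 0.24 for LAMA4, 9.81 ± 0.93 for COL3A1, 11.61 ± 0.45 for BGN and 6.07 ± 0.38 for POSTN, encoding a laminin chain, the type III collagen chain, biglycan and periostin. APOE (8.74 ± 0.64), the sulfatase SULF2 (9.53 ± 0.57), the chemerin receptor CMKLR1 (8.94 ± 0.53), the chitinase-like CHI3L1 (8.35 ± 1.10) and the calprotectin subunit S100A9 (8.24 ± 0.52) rose as well. The largest falls were in CCBE1 (-9.23 ± 0.20), RIPOR2 (-8.41 ± 0.57), SULT1B1 (-8.30 ± 0.28), aldehyde oxidase AOX1 (-6.14 ± 0.23), the IL-33 receptor IL1RL1 (-6.05 ± 0.54), PLAC8 (-5.45 ± 0.24), the Wnt inhibitor DKK1 (-5.33 ± 0.47) and GPM6B (-5.06 ± 0.38). Of 16323 genes tested, 5433 rose and 4965 fell, and 4677 of them changed at least 2-fold.

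Genes were also tested as lists, with the adjusted p of camera given first at a preset correlation between genes and then with the correlation estimated (marked estimated). Numbers of members that passed were the same with the p adjusted over the list alone unless a second pair of numbers is given. Matrix genes moved as lists. Of the collagens, 20 of 23 tested members rose and 1 fell (camera adjusted p = 6.4e-08, 0.088 estimated), with COL6A1 at 5.31 ± 0.17, COL6A2 at 4.13 ± 0.13 and COL5A3 at 6.35 ± 0.34, and the faller COL8A1 at -2.70 ± 0.15. In addition 26 of 34 matrix glycoproteins and proteoglycans rose and 5 fell (camera adjusted p = 1.8e-05, 0.14 estimated), and versican VCAN had 3.67 ± 0.14. Proteolysis genes followed: 20 of 26 matrix proteases and inhibitors rose and 4 fell (camera adjusted p = 4.2e-04, 0.040 estimated), a call that held with the estimated correlation. Among them the urokinase gene PLAU (3.87 ± 0.12), SERPINE2 (4.13 ± 0.16) and the membrane protease gene MMP14 (3.14 ± 0.24) rose. Basal epithelial genes rose as well, with TP63 at 5.16 ± 0.27, KRT16 at 7.92 ± 0.43, KRT17 at 7.75 ± 0.45 and P-cadherin CDH3 at 7.32 ± 0.40, and 12 of 16 basal keratins and myoepithelial markers rose and 2 fell (13 and 2 over the list alone, camera adjusted p = 0.0021, 0.32 estimated).

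Genes of antiviral defence and antigen display were higher in tumorspheres. OAS1 had 5.80 ± 0.43 and IFI44L 3.29 ± 0.26, and 31 of 37 interferon-stimulated genes rose and 0 fell (camera adjusted p = 1.5e-06, 0.38 estimated). HLA-B had 2.32 ± 0.21, and 21 of 25 antigen presentation genes rose and 3 fell (camera adjusted p = 9.2e-05, 0.32 estimated). NF-kB targets included LIF (3.99 ± 0.26), CXCL1 (2.87 ± 0.21) and TNFAIP3 (1.95 ± 0.13), and 22 of 27 of that list rose and 2 fell (camera adjusted p = 4.2e-05, 0.088 estimated); BIRC3 fell (-1.92 ± 0.11). DUSP4 (3.51 ± 0.17) and DUSP6 (5.41 ± 0.26), phosphatases that damp ERK signalling, rose, and 16 of 22 ERK feedback and FGF response genes rose and 3 fell (camera adjusted p = 9.2e-05, 0.14 estimated). GDF15 (5.61 ± 0.30) and the cell cycle inhibitor CDKN1A (2.13 ± 0.17) stood among p53 targets, of which 18 rose and 2 fell (18 and 3 over the list alone, camera adjusted p = 1.8e-04, 0.088 estimated). AKR1C1 (4.54 ± 0.35) and NQO1 (2.15 ± 0.19) stood among NRF2 targets and redox enzymes, of which 19 rose and 3 fell (camera adjusted p = 1.4e-04, 0.32 estimated). The cathepsin gene CTSF had 3.16 ± 0.20, and 19 of 26 lysosome and autophagy genes rose and 3 fell (camera adjusted p = 3.9e-04, 0.32 estimated).

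Genes of cell division and energy metabolism were lower in tumorspheres. CDC20 (-2.37 ± 0.16), KIF20A (-1.67 ± 0.12) and TPX2 (-1.93 ± 0.15) fell with the proliferation list, of which 32 fell and 0 rose (camera adjusted p = 2.0e-15, 0.32 estimated). Oxidative phosphorylation genes had a median log2 fold change of -0.40, and 26 fell and 0 rose (camera adjusted p = 8.0e-07, 0.32 estimated). The hexokinase gene HK2 had -1.48 ± 0.14, and 14 of 19 glycolysis genes fell and 2 rose (camera adjusted p = 3.1e-04, 0.36 estimated). GADD45B had -3.35 ± 0.11, and 16 of 25 YAP and TAZ targets fell and 3 rose (camera adjusted p = 2.2e-04, 0.088 estimated), IGFBP3 (6.26 ± 0.31) being among those that rose. For targets of the glucocorticoid receptor, whose ligand hydrocortisone was in the 2D medium alone, 13 of 22 tested members fell and 5 rose (13 and 6 over the list alone, camera adjusted p = 0.017, 0.33 estimated), with FKBP5 at -1.96 ± 0.14. Of the cytosolic heat shock genes 13 of 18 tested members fell and 2 rose (camera adjusted p = 0.0045, 0.33 estimated), with CRYAB at -3.66 ± 0.45. Of the metallothioneins 7 of 10 tested members fell and 1 rose (camera adjusted p = 0.033, 0.32 estimated), with MT2A at -1.92 ± 0.16.

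Markers of other cell types did not pass the list test: of leukocyte markers 2 fell and 1 rose (2 and 0 over the list alone, camera adjusted p = 0.74, 0.82 estimated), and of endothelial markers 3 fell and 1 rose (camera adjusted p = 0.47, 0.67 estimated). The neural markers had 4 tested members, of which 2 fell, and the mitochondrially encoded transcripts 2, of which 1 fell, too few for that test. Without the libraries that stand apart (an alternative chosen after the data were seen), 11395 genes passed in wt 3D against 2D. Medium, RNA kit and culture format change together between 2D and 3D, so this comparison does not separate them.

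The same change of culture was measured in each pool. LAMA4 rose in both, with log2 fold changes of 7.95 ± 0.20 in labelled KOs and 8.75 ± 0.21 in KOd, as did COL3A1 (8.19 ± 0.86 and 9.27 ± 0.92), S100A9 (9.67 ± 0.35 and 13.04 ± 0.46), CHI3L1 (10.84 ± 0.87 and 12.68 ± 1.12), the carboxylesterase CES1 (7.19 ± 0.23 and 8.08 ± 0.27) and APOE (6.24 ± 0.57 and 7.84 ± 0.61). CCBE1 fell in both, with -5.39 ± 0.16 and -6.97 ± 0.20, as did RIPOR2 (-7.56 ± 0.43 and -5.48 ± 0.41) and INSC (-5.19 ± 0.36 and -6.21 ± 0.41). IL1B (6.41 ± 0.23 and 3.37 ± 0.23) and NOTCH3 (5.84 ± 0.49 and 7.91 ± 0.58) rose in both too, and the BMP target ID3 (-5.27 ± 0.43 and -2.11 ± 0.37) and KRT80 (-4.20 ± 0.18 and -5.42 ± 0.19) fell. In labelled KOs 5367 genes rose and 5247 fell (6762 rose and 3565 fell with scaling by library totals alone), and in KOd 5742 rose and 5089 fell. In 3D against 2D, 2643 genes rose and 2594 fell in wt and both pools alike. Across the 16323 genes, which are not independent replicates, the log2 fold changes correlated between wt and labelled KOs with r = 0.644 (Spearman 0.640), between wt and KOd with r = 0.783 (0.724) and between the pools with r = 0.700 (0.635). Of the genes that passed in both members of each pair, 90.5% of 7416, 92.7% of 7840 and 87.1% of 7643 moved the same way. Without the libraries that stand apart, 12255 genes passed in labelled KOs and 12005 in KOd.

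NF-kB targets rose in the tumorspheres of both pools, with the chemokine CXCL1 at 8.29 ± 0.26 in labelled KOs and 2.03 ± 0.20 in KOd. In labelled KOs 26 of 27 NF-kB targets, cytokines and chemokines rose and 1 fell (camera adjusted p = 5.0e-12, 0.013 estimated). In KOd 21 rose and 1 fell (22 and 1 over the list alone, camera adjusted p = 2.5e-04, 0.18 estimated). Genes of the ATF4 and amino acid response fell in KOd tumorspheres, among them the asparagine synthetase gene ASNS (-5.32 ± 0.22), which shares reads with an overlapping readthrough gene, TRIB3 (-3.08 ± 0.12) and MTHFD2 (-2.27 ± 0.08). In labelled KOs 17 of 29 ATF4 and amino acid response genes fell and 6 rose (camera adjusted p = 0.025, 0.55 estimated). In KOd 27 fell and 0 rose (camera adjusted p = 4.1e-14, 0.042 estimated). COL6A1 had 3.25 ± 0.15 in labelled KOs and 4.28 ± 0.16 in KOd. In labelled KOs 17 of 23 collagens rose and 3 fell (camera adjusted p = 9.7e-05, 0.50 estimated). In KOd 16 rose and 2 fell (camera adjusted p = 4.0e-04, 0.32 estimated). In labelled KOs 17 of 26 matrix proteases and inhibitors rose and 5 fell (camera adjusted p = 0.0056, 0.075 estimated). In KOd 20 rose and 2 fell (camera adjusted p = 2.1e-04, 0.023 estimated). OAS1 had 5.13 ± 0.52 and 6.37 ± 0.47, and CDC20 -1.76 ± 0.15 and -2.57 ± 0.16. In labelled KOs 31 of 37 interferon-stimulated genes rose and 0 fell (camera adjusted p = 1.8e-07, 0.55 estimated). In KOd 32 rose and 1 fell (camera adjusted p = 5.0e-06, 0.52 estimated). In labelled KOs 27 of 32 proliferation genes fell and 3 rose (camera adjusted p = 3.3e-05, 0.56 estimated). In KOd 31 fell and 0 rose (camera adjusted p = 1.7e-10, 0.38 estimated). RPSA had -1.34 ± 0.10 and -1.06 ± 0.10. In labelled KOs 36 of 36 cytosolic ribosomal proteins fell and 0 rose (camera adjusted p = 4.6e-10, 0.55 estimated). In KOd 28 fell and 0 rose (camera adjusted p = 8.3e-06, 0.57 estimated). HSPA1A, which shares reads with HSPA1B, rose in KOd (3.90 ± 0.17), as did HSPA8 (1.99 ± 0.14), and 8 of 18 cytosolic heat shock genes rose and 1 fell (camera adjusted p = 0.045, 0.54 estimated) there.

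Adherent wt cells moved to tumorsphere medium were compared with adherent wt cells in 2D medium and with tumorspheres. The log2 fold changes in them were 6.65 ± 0.28 for IL1B, 5.44 ± 0.33 for IL1A, 4.21 ± 0.20 for CCL20 and 3.48 ± 0.28 for LIF, and other rises were those of the protease inhibitor TFPI2 (8.76 ± 0.48), BMP2 (5.13 ± 0.40), IL1RL1 (5.36 ± 0.40), TSPAN18 (5.73 ± 0.43) and S100A9 (5.32 ± 0.72). THBS1 (-4.48 ± 0.36), POSTN (-4.30 ± 0.59) and FN1 (-2.32 ± 0.24) fell, as did DKK1 (-4.79 ± 0.55), the neuregulin gene NRG1 (-4.18 ± 0.56), NEDD9 (-4.11 ± 0.55), SLC8A1 (-4.30 ± 0.31) and OLFML3 (-6.87 ± 1.42). For NF-kB targets, 21 of 27 tested members rose and 1 fell (camera adjusted p = 1.4e-19, 0.0013 estimated), and for YAP and TAZ targets 17 fell and 2 rose (camera adjusted p = 1.8e-08, 0.0056 estimated), with CCN1 at -2.64 ± 0.17 and CCN2 at -2.82 ± 0.26. Both calls held with the estimated correlation. Metallothioneins bind zinc and copper, and 8 of 10 of them rose and 0 fell (camera adjusted p = 1.0e-04, 0.091 estimated), with MT1X at 2.23 ± 0.19. DUSP6 reached 3.88 ± 0.25, and 12 of 22 ERK feedback and FGF response genes rose and 0 fell (camera adjusted p = 1.5e-06, 0.11 estimated), in a medium that holds EGF and basic FGF, each at 20 ng/mL. N-cadherin CDH2 had -1.08 ± 0.09, and 12 of 22 mesenchymal markers and EMT regulators fell and 1 rose (camera adjusted p = 4.7e-04, 0.14 estimated). Of the cholesterol biosynthesis genes 8 of 25 tested members rose and 1 fell (9 and 1 over the list alone, camera adjusted p = 0.0013, 0.64 estimated). NAMPT, which makes the NAD precursor from nicotinamide, had 1.56 ± 0.14, and 10 of 30 NAD, methionine and one-carbon genes rose and 3 fell (camera adjusted p = 0.048, 0.15 estimated). In all 2546 genes rose and 2678 fell (2637 rose and 2465 fell with scaling by library totals alone). With only 2 such libraries this count rested on each of them: 3192 genes passed without replicate A and 2752 without replicate B, and 7968 passed without the libraries that stand apart, none of which is in this comparison.

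Set beside the change in tumorspheres, 1034 of the 2546 genes that rose with medium also rose in 3D and 622 fell there, and of the 2678 that fell with medium 1238 fell in 3D and 654 rose. Of the 3548 genes that passed in both, 64.0% moved the same way. The correlation across genes was r = 0.236, below the 0.446 that unchanged simulated groups gave against the same wt 2D libraries, but the covariance was 0.432 against 0.101. In the same direction 2272 genes passed in both, against a simulated mean of 0. That 0 was fixed beforehand, since groups without change give almost no calls, and it does not measure what medium and 3D share. IL1RL1 was -11.41 ± 0.56 in 3D against tumorsphere medium, TFPI2 -8.26 ± 0.47, POSTN 10.36 ± 0.60, KRT17 10.30 ± 0.66 and OLFML3 9.76 ± 1.35. This comparison changes format and time in culture together, and the RNA kit too where the cells in tumorsphere medium had that of 2D. In 3D against tumorsphere medium, 20 of 23 collagens rose and 1 fell (camera adjusted p = 1.1e-08, 0.13 estimated). NF-kB targets were lower there, and 19 fell and 5 rose (19 and 6 over the list alone, camera adjusted p = 8.7e-04, 0.18 estimated). Of the proliferation genes 28 of 32 tested members fell and 0 rose (camera adjusted p = 4.3e-11, 0.39 estimated). In all 5358 genes rose and 4896 fell (11426 passed without the libraries that stand apart).

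**Figure D2:**
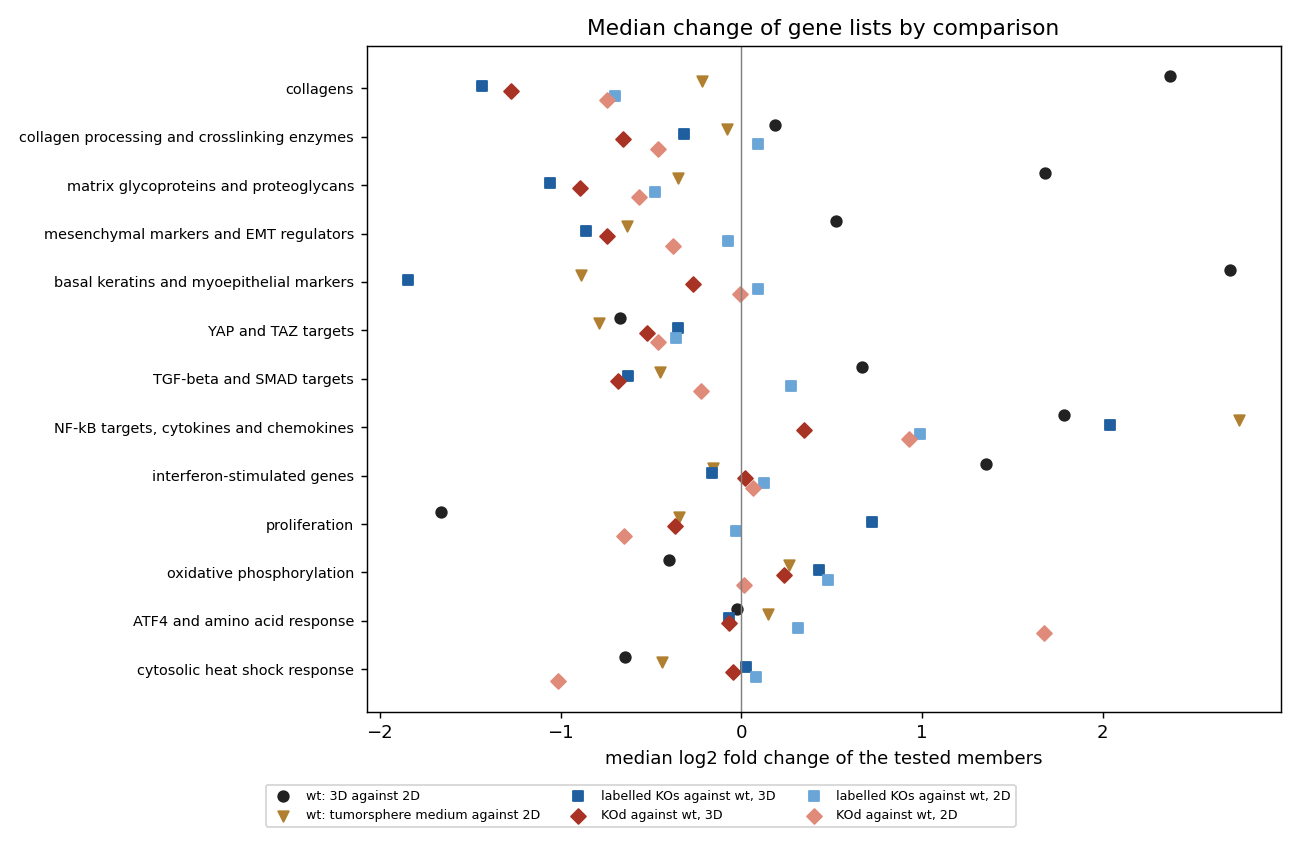
Median log2 fold change of the tested members of 13 gene lists in 6 comparisons, 1 symbol per comparison, on a linear axis with a grey line at 0. Collagens stood at 2.37 for wt tumorspheres against 2D, and at -1.43 for labelled KOs and -1.28 for KOd against wt in 3D.

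The next comparisons ask how cells of the pools differ from wt in the same culture. In 2D, COL1A1 (Entrez 1277, chromosome 17, 50184101 to 50201631), the main chain of type I collagen, fell from 475 ± 104 CPM in wt (mean ± SD, n = 3) to 20.7 ± 6.58 in labelled KOs and 28.8 ± 5.44 in KOd. Log2 fold changes of COL1A1 were -4.52 ± 0.23 in labelled KOs and -4.05 ± 0.23 in KOd, and those of COL12A1 were -4.08 ± 0.36 and -3.43 ± 0.35. COL4A4 (-3.81 ± 0.46 and -4.51 ± 0.49), DKK1 (-2.85 ± 0.42 and -3.00 ± 0.42), the aldolase gene ALDOC (-3.71 ± 0.32 and -3.97 ± 0.34), FHAD1 (-3.09 ± 0.20 and -2.88 ± 0.21) and the cancer-testis genes MAGEC1 (-6.97 ± 0.22 and -4.92 ± 0.19) and MAGEA11 (-3.64 ± 0.19 and -5.06 ± 0.21) fell in both pools. CD33 (2.90 ± 0.10 and 2.81 ± 0.10), BMERB1 (3.81 ± 0.16 and 2.52 ± 0.16), TSPAN18 (6.93 ± 0.41 and 2.48 ± 0.49), IL6 (2.72 ± 0.29 and 2.46 ± 0.29), RCCD1 (2.44 ± 0.24 and 2.84 ± 0.24), the angiotensinogen gene AGT (3.04 ± 0.59 and 2.20 ± 0.59) and DUSP6 (2.36 ± 0.23 and 2.19 ± 0.24) rose in both. In all 4524 genes rose and 4157 fell in labelled KOs, 3611 rose and 3669 fell in KOd (4490 rose and 2842 fell with scaling by library totals alone), and 1351 rose and 1414 fell in both pools. For the mean of the pools, 3502 rose and 3664 fell. With library totals alone 4040 rose and 4450 fell in labelled KOs, 1546 rose and 1215 fell in both pools and 3788 rose and 3280 fell for the mean of the pools, so which direction held more genes depended on the scaling.

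In labelled KOs 14 of 23 collagens fell and 3 rose (camera adjusted p = 0.035, 0.48 estimated). In KOd 14 fell and 1 rose (15 and 1 over the list alone, camera adjusted p = 1.8e-04, 0.28 estimated). COL4A1 (-5.84 ± 0.39 in KOd) and COL4A2 (-4.53 ± 0.28) lie in a stretch of chromosome 13 whose genes were low together in both pools, with medians of -1.19 in labelled KOs and -0.82 in KOd. The YAP and TAZ target CCN2 fell in KOd (-3.46 ± 0.23), and its change in labelled KOs did not pass. In labelled KOs 13 of 25 YAP and TAZ targets fell and 0 rose (camera adjusted p = 3.0e-04, 0.21 estimated). In KOd 16 fell and 4 rose (18 and 5 over the list alone, camera adjusted p = 0.0011, 0.14 estimated). The stress genes GDF15 (5.83 ± 0.30), SESN2 (4.01 ± 0.28) and TRIB3 (3.75 ± 0.13) and the cystathionine lyase gene CTH (3.64 ± 0.20) stood among the largest rises in KOd. In labelled KOs 13 of 29 ATF4 and amino acid response genes rose and 3 fell (camera adjusted p = 0.11, 0.64 estimated). In KOd 27 rose and 0 fell (camera adjusted p = 2.9e-21, 0.016 estimated). HSPA8 had -2.78 ± 0.14 in KOd, and 15 of 18 cytosolic heat shock genes fell and 0 rose (16 and 0 over the list alone, camera adjusted p = 4.1e-09, 0.14 estimated) there. Of the glycolysis genes in KOd, 16 of 19 tested members fell and 1 rose (camera adjusted p = 1.1e-05, 0.31 estimated), with LDHA, in a window low in labelled KOs 2D, at -0.96 ± 0.15. In labelled KOs the ribosomal protein RPS18 had 0.70 ± 0.12, and 33 of 36 cytosolic ribosomal proteins rose and 0 fell (34 and 0 over the list alone, camera adjusted p = 3.8e-09, 0.48 estimated). In labelled KOs too, 25 of 32 oxidative phosphorylation genes rose and 3 fell (26 and 3 over the list alone, camera adjusted p = 5.6e-06, 0.48 estimated). The list of histone H3K9 and H3K27 methylation enzymes also holds DNA methylation enzymes such as DNMT1 and proteins that bind these marks, such as CBX5. In labelled KOs 21 of 33 genes of this list fell and 0 rose (22 and 0 over the list alone, camera adjusted p = 1.8e-04, 0.26 estimated). In KOd 15 fell and 9 rose (16 and 9 over the list alone, camera adjusted p = 0.34, 0.68 estimated). In labelled KOs 9 of 30 NAD, methionine and one-carbon genes rose and 8 fell (camera adjusted p = 0.67, 0.90 estimated). In KOd 10 rose and 9 fell (11 and 10 over the list alone, camera adjusted p = 0.77, 0.87 estimated).

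Of the 4366 genes that passed in both pools in 2D, 63.3% moved the same way. The shared 1351 rises compare with 1001 for independent lists and the 1414 falls with 934. Across genes the log2 fold changes of the pools correlated with r = 0.527, and unchanged simulated groups against the same wt libraries gave 0.545. Their covariance was 0.689 against 0.103 in the simulated groups. A mean of 0 simulated genes passed in both in the same direction, against 2765 measured. Groups without change give almost no calls, so that 0 was fixed beforehand and does not measure what the pools share. Part of the excess over independent lists can come from the shared controls, here and in 3D. Without the libraries that stand apart 3824 genes passed in both pools, 10304 in labelled KOs, 9659 in KOd and 9388 for the mean of the pools. NNMT mRNA does not check the KOs label. In 28 windows of 10 Mb genes were shifted together in labelled KOs 2D. Genes in these windows with a mean log2 CPM over 3 made up 10.9% of the genes called in both pools and 5.80% of the tested genes. Genes below that level were not counted in the windows but stand in both totals, so the difference does not separate position from expression level. The windows were also chosen by the change in labelled KOs 2D, 1 of the 2 calls counted here, so a higher share was built in.

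In tumorspheres type I collagen stood far lower in the pools than in wt. COL1A1 had 4330 ± 992 CPM in wt (mean ± SD, n = 3), 31.8 ± 2.36 in labelled KOs and 77.7 ± 5.68 in KOd, with log2 fold changes of -7.09 ± 0.26 and -5.80 ± 0.24. COL1A2, with 2 to 9 reads per library in the pools, fell with -8.08 ± 0.45 and -7.76 ± 0.45, COL12A1 with -4.66 ± 0.37 and -5.96 ± 0.40, COL13A1 with -5.39 ± 0.34 and -3.90 ± 0.32, and the collagen crosslinking gene LOX with -5.21 ± 0.37 and -4.45 ± 0.36. OLFML3 (-3.70 ± 0.67 and -4.88 ± 0.73), MAGEC1 (-5.74 ± 0.20 and -3.97 ± 0.18), MAGEA11 (-4.28 ± 0.19 and -4.93 ± 0.20) and TNFRSF19 (-5.02 ± 0.21 and -3.93 ± 0.20), the last in a stretch of chromosome 13 that was low in the pools, fell as well. S100A9 (5.81 ± 0.29 and 5.44 ± 0.28), the lipocalin LCN2 (10.78 ± 0.55 and 6.55 ± 0.70), serum amyloid SAA1 (7.26 ± 0.31 and 4.29 ± 0.28) and SAA2 (7.36 ± 0.36 and 4.42 ± 0.32), the last 2 of which share reads, rose in both. AQP9 (6.84 ± 0.33 and 4.67 ± 0.32), BACE2 (5.88 ± 0.23 and 4.53 ± 0.23), MYBPC1 (4.28 ± 0.79 and 5.52 ± 0.77) and SGPP2 (4.15 ± 0.68 and 4.05 ± 0.68) rose too. In all 4535 genes rose and 4655 fell in labelled KOs (6039 rose and 3538 fell with scaling by library totals alone), 2689 rose and 2859 fell in KOd (4199 rose and 1793 fell with scaling by library totals alone), and 1748 rose and 1941 fell in both (2784 rose and 1222 fell with scaling by library totals alone). For the mean of the pools 3677 rose and 4146 fell (5426 rose and 2816 fell with scaling by library totals alone).

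In labelled KOs 18 of 23 collagens fell and 4 rose (camera adjusted p = 1.6e-04, 0.33 estimated). In KOd 17 fell and 1 rose (camera adjusted p = 6.7e-12, 0.058 estimated). Biglycan BGN had -4.91 ± 0.28 in labelled KOs and -1.53 ± 0.24 in KOd, periostin POSTN -4.58 ± 0.35 in labelled KOs and -2.93 ± 0.32 in KOd, and SPARC -2.15 ± 0.17 in labelled KOs and -1.85 ± 0.16 in KOd, and POSTN lies in a stretch that was low in both pools and BGN in 1 that was high in labelled KOs. In labelled KOs 22 of 34 matrix glycoproteins and proteoglycans fell and 6 rose (camera adjusted p = 3.4e-04, 0.33 estimated). In KOd 20 fell and 6 rose (camera adjusted p = 2.4e-05, 0.24 estimated). PLOD2, which hydroxylates collagen lysines, had -2.05 ± 0.09 in labelled KOs and -1.39 ± 0.09 in KOd. In labelled KOs 14 of 25 collagen processing and crosslinking enzymes fell and 2 rose (camera adjusted p = 0.030, 0.74 estimated). In KOd 17 fell and 1 rose (19 and 1 over the list alone, camera adjusted p = 5.3e-08, 0.28 estimated). SNAI2, a transcription factor of the epithelial-mesenchymal transition, had -1.75 ± 0.14 in labelled KOs and -1.86 ± 0.14 in KOd. In labelled KOs 16 of 22 mesenchymal markers and EMT regulators fell and 1 rose (17 and 2 over the list alone, camera adjusted p = 3.4e-04, 0.21 estimated). In KOd 14 fell and 0 rose (15 and 0 over the list alone, camera adjusted p = 5.4e-08, 0.057 estimated). PMEPA1, a feedback gene of TGF-beta signalling, had -2.36 ± 0.16 in labelled KOs and -3.10 ± 0.17 in KOd, and IGFBP3 had -9.78 ± 0.40 in labelled KOs and -7.46 ± 0.34 in KOd. In labelled KOs 11 of 22 TGF-beta and SMAD targets fell and 4 rose (camera adjusted p = 0.062, 0.45 estimated). In KOd 12 fell and 2 rose (camera adjusted p = 3.1e-04, 0.092 estimated).

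Cytokine genes were higher in the tumorspheres of both pools: IL1B had 5.30 ± 0.22 in labelled KOs and 1.41 ± 0.20 in KOd, and CCL20 4.18 ± 0.20 in labelled KOs and 1.05 ± 0.20 in KOd. In labelled KOs 20 of 27 NF-kB targets, cytokines and chemokines rose and 0 fell (21 and 0 over the list alone, camera adjusted p = 1.8e-08, 0.046 estimated). In KOd 11 rose and 3 fell (camera adjusted p = 0.039, 0.37 estimated). The call held with the estimated correlation in labelled KOs. NDUFV1, a subunit of respiratory complex I whose gene lies in a window low in labelled KOs 2D, had 0.79 ± 0.07 in labelled KOs and 0.74 ± 0.07 in KOd. In labelled KOs 24 of 32 oxidative phosphorylation genes rose and 1 fell (camera adjusted p = 1.3e-04, 0.52 estimated). In KOd 16 rose and 0 fell (17 and 0 over the list alone, camera adjusted p = 3.5e-05, 0.39 estimated). Basal keratin KRT14 had -4.29 ± 0.42 in labelled KOs, where 11 of 16 basal keratins and myoepithelial markers fell and 0 rose (camera adjusted p = 1.6e-04, 0.33 estimated). In labelled KOs 27 of 32 proliferation genes rose and 1 fell (28 and 1 over the list alone, camera adjusted p = 6.2e-07, 0.61 estimated). In KOd 11 fell and 0 rose (camera adjusted p = 0.029, 0.89 estimated). In labelled KOs 3 of 8 endothelial markers rose and 1 fell (camera adjusted p = 0.40, 0.74 estimated). In KOd 4 rose and 0 fell (camera adjusted p = 0.039, 0.31 estimated).

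Of the 4108 genes that passed in both pools in 3D, 89.8% moved the same way, and the 1748 shared rises and 1941 shared falls compare with 747 and 815 for independent lists. The correlation across genes was r = 0.682, against 0.523 in simulated unchanged groups with the same controls, and the covariance 1.18 against 0.0619. Without the libraries that stand apart 4564 genes passed in both pools, 10489 in labelled KOs, 7331 in KOd and 9009 for the mean of the pools. As in 2D the KOs label is unchecked. Genes with a mean log2 CPM over 3 in the windows shifted in labelled KOs 2D made up 11.0% of the genes called in both pools. They made up 5.80% of the tested genes, and again the difference does not separate position from expression level.

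**Figure D3:**
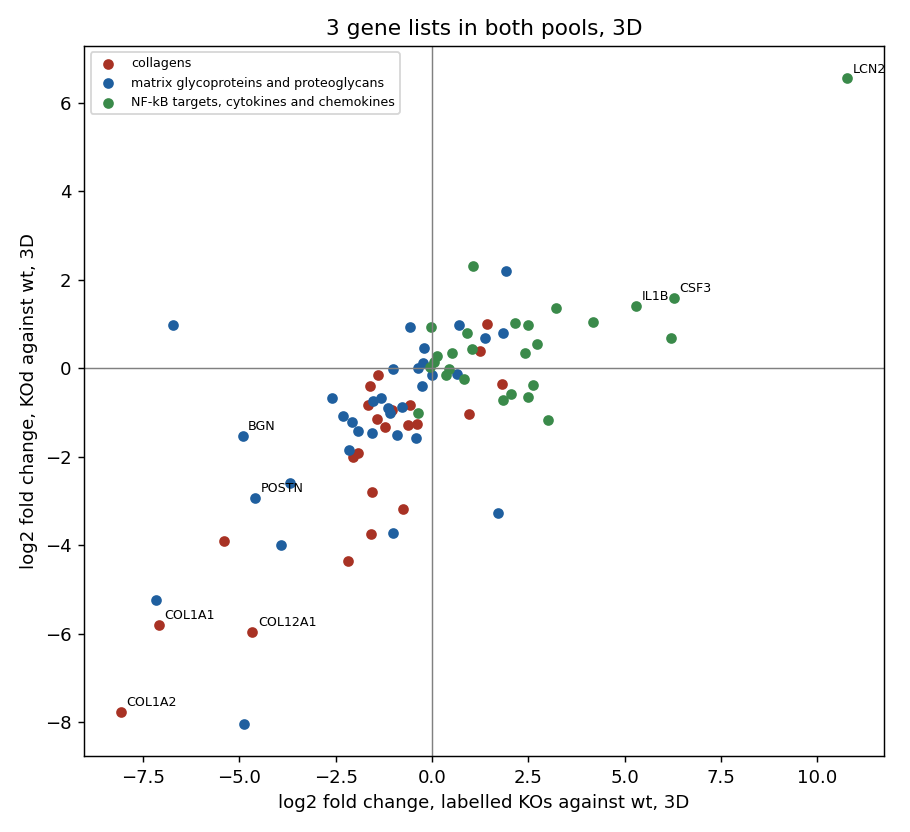
Log2 fold change against wt in 3D of the genes of 3 lists, with labelled KOs on the x axis and KOd on the y axis, 1 point per gene and grey lines at 0. COL1A1, at -7.09 and -5.80, and COL1A2 lie low on both axes, and LCN2 lies high on both.

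Whether culture acted differently in the pools was tested as an interaction, the 3D against 2D change in the mean of the pools minus that in wt. SAA1 had an interaction of 4.17 ± 0.33 (log2 ± SE), SAA2 of 4.35 ± 0.40, SULT1B1 of 4.10 ± 0.36, TFPI2 of 3.35 ± 0.52, PLEKHA7 of 3.35 ± 0.47, CES1P2 of 3.22 ± 0.27 and the non-muscle myosin gene MYH10 of 3.17 ± 0.26, each a larger rise or a smaller fall with culture in the pools than in wt. On the other side stood TNFRSF19 (-5.05 ± 0.26), the carboxypeptidase gene CPE (-4.82 ± 0.43), the guidance genes SEMA3A (-3.78 ± 0.35) and UNC5B (-3.60 ± 0.60), OLFML3 (-3.74 ± 0.80), the cadherin gene CDH6 (-3.47 ± 0.34), KRT17 (-3.42 ± 0.49) and BMERB1 (-3.37 ± 0.18). SAA1, SAA2, PLEKHA7, TNFRSF19 and CPE lie in windows that were low in labelled KOs 2D, and MYH10 in 1 that was high. In all 2472 genes had a positive and 2627 a negative interaction (positive share 48.5% with TMM and 65.5% with library totals alone). In labelled KOs alone 2917 were positive and 3095 negative (positive share 48.5% with TMM and 69.5% with library totals alone), and in KOd alone 2347 and 2404 (49.4% with TMM and 55.6% with library totals alone).

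TRIB3 (-2.12 ± 0.14), CEBPG (-1.18 ± 0.11) and SARS1 (-0.95 ± 0.10) had negative interactions, and 24 of 29 ATF4 and amino acid response genes were negative and 0 positive (25 and 0 over the list alone, camera adjusted p = 4.8e-18, 0.032 estimated), a call that held with the estimated correlation. HSPA8 had 1.29 ± 0.16, and 14 of 18 cytosolic heat shock genes were positive and 0 negative (camera adjusted p = 4.3e-07, 0.21 estimated). MCM6 had 0.84 ± 0.15, and 24 of 32 proliferation genes were positive and 0 negative (26 and 0 over the list alone, camera adjusted p = 2.2e-09, 0.58 estimated). In labelled KOs alone 29 were positive and 0 negative (30 and 0 over the list alone, camera adjusted p = 2.4e-11, 0.51 estimated), and in KOd alone 8 were positive and 1 negative (camera adjusted p = 0.0062, 0.78 estimated). The other lists are given for the mean of the pools, in which 1 pool can carry a result. PMEPA1 (-2.73 ± 0.19), LTBP2 (-2.89 ± 0.23) and SMAD7 (-1.07 ± 0.12) stood among TGF-beta and SMAD targets, of which 14 were negative and 0 positive (camera adjusted p = 2.6e-05, 0.081 estimated). COL1A1 had -2.16 ± 0.25 and COL6A1 -1.55 ± 0.17, and 10 of 23 collagens were negative and 4 positive (12 and 5 over the list alone, camera adjusted p = 0.0073, 0.56 estimated). PCOLCE had -2.02 ± 0.32, and 10 of 25 collagen processing and crosslinking enzymes were negative and 1 positive (12 and 1 over the list alone, camera adjusted p = 0.0084, 0.60 estimated). SNAI2 had -1.82 ± 0.17, and 12 of 22 mesenchymal markers and EMT regulators were negative and 2 positive (camera adjusted p = 0.0084, 0.36 estimated). TP63 had -2.85 ± 0.29, and 10 of 16 basal keratins and myoepithelial markers were negative and 0 positive (11 and 1 over the list alone, camera adjusted p = 0.0068, 0.49 estimated). GDF15 had -3.03 ± 0.34, and 12 of 23 p53 targets were negative and 0 positive (camera adjusted p = 0.0010, 0.21 estimated). HK2 had 1.66 ± 0.17, and 8 of 19 glycolysis genes were positive and 2 negative (11 and 2 over the list alone, camera adjusted p = 0.0053, 0.58 estimated). SPRED1 had -1.10 ± 0.10, and 9 of 22 ERK feedback and FGF response genes were negative and 1 positive (10 and 1 over the list alone, camera adjusted p = 0.0070, 0.49 estimated). MT1X had 1.61 ± 0.21, and 5 of 10 metallothioneins were positive and 0 negative (camera adjusted p = 0.017, 0.36 estimated). RPSA had -0.62 ± 0.12, and 22 of 36 cytosolic ribosomal proteins were negative and 0 positive (29 and 0 over the list alone, camera adjusted p = 6.8e-08, 0.58 estimated). Without the libraries that stand apart 6577 genes had an interaction in the mean of the pools, 7447 in labelled KOs and 6800 in KOd.

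The pools were also compared with each other. In both cultures PALD1 was higher in KOd than in labelled KOs, with log2 fold changes of 5.63 ± 0.26 in 2D and 5.93 ± 0.27 in 3D, and NNMT was lower (-4.54 ± 0.21 and -4.04 ± 0.20). In 2D DNAJC15 (4.56 ± 0.17), the nuclear RNA NEAT1 (4.20 ± 0.51), SNHG1 (3.99 ± 0.21), GDF15 (3.72 ± 0.25), FGF13 (3.78 ± 0.19) and TFAP2A (3.62 ± 0.16) were higher in KOd, and ADGRL2 (-5.62 ± 0.25), TNFRSF21 (-4.88 ± 0.22), DUSP2 (-4.03 ± 0.37), ANGPTL4 (-4.01 ± 0.52) and osteopontin SPP1 (-3.83 ± 0.41) lower. In 3D H19 (4.66 ± 0.50), ANXA8 (4.27 ± 0.15, which shares reads with a close paralog), LDOC1 (4.14 ± 0.18) and TP73 (3.85 ± 0.34) were higher in KOd, and decorin DCN (-4.98 ± 0.18), AOX1 (-4.17 ± 0.21), CCN4 (-4.08 ± 0.18), TFPI2 (-4.03 ± 0.37) and IL1B (-3.89 ± 0.20) lower. DNAJC15, NEAT1 and SNHG1 lie in stretches of chromosomes 13 and 11 whose genes were low together in labelled KOs. In 2D 4704 genes were higher and 5017 lower in KOd (share higher 48.4% with TMM and 59.8% with library totals alone), and in 3D 3907 were higher and 3803 lower (50.7% with TMM and 49.6% with library totals alone).

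In 2D TRIB3 was higher in KOd (2.61 ± 0.12), and 27 of 29 ATF4 and amino acid response genes were higher and 0 were lower (camera adjusted p = 2.4e-12, 0.13 estimated). HSPA8 was lower (-3.11 ± 0.14), and 13 of 18 cytosolic heat shock genes were lower and 2 were higher (camera adjusted p = 1.1e-04, 0.41 estimated). NSDHL, in a window high in labelled KOs, was lower too (-1.84 ± 0.16), and 17 of 25 cholesterol biosynthesis genes were lower and 0 were higher (18 and 0 over the list alone, camera adjusted p = 0.023, 0.70 estimated). Of the cancer-testis genes 11 of 18 tested members were lower and 3 were higher (camera adjusted p = 0.013, 0.41 estimated), with PAGE5 at -1.53 ± 0.09. Of the oxidative phosphorylation genes 25 of 32 tested members were lower and 3 were higher (camera adjusted p = 5.7e-05, 0.56 estimated), with NDUFB3 at -1.42 ± 0.10. In 3D the basal genes CDH3 (6.64 ± 0.37), KRT16 (3.62 ± 0.26) and KRT17 (3.24 ± 0.34) were higher in KOd, and 12 of 16 basal keratins and myoepithelial markers were higher and 0 were lower (camera adjusted p = 1.7e-05, 0.27 estimated). CXCL1 (-3.00 ± 0.17) and LIF (-3.14 ± 0.21) were lower, and 19 of 27 NF-kB targets, cytokines and chemokines were lower and 2 were higher (camera adjusted p = 4.4e-08, 0.071 estimated). CDC20 was lower (-1.48 ± 0.15), and 31 of 32 proliferation genes were lower and 0 were higher (camera adjusted p = 1.2e-12, 0.65 estimated). MT1X was lower (-2.67 ± 0.18), and 8 of 10 metallothioneins were lower and 0 were higher (9 and 0 over the list alone, camera adjusted p = 2.3e-04, 0.18 estimated). ZMAT3 was higher (1.91 ± 0.08), and 14 of 23 p53 targets were higher and 4 were lower (camera adjusted p = 0.0017, 0.27 estimated). The libraries labelled KOs had lower ribosomal RNA shares and larger totals than the KOd libraries, and without the libraries that stand apart 11302 genes differed between the pools in 2D and 9816 in 3D.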

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

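The tests of copy number, of the step at NNMT, of neighbouring genes, of a common descent of the pools, of a wrong label and of other splits of the libraries were chosen after the result was seen. A difference between groups under the same contrast, tested as an interaction or between the pools, marked the results of this part. The culture change differed from that of wt for 5099 genes in the mean of the pools, 6012 in labelled KOs and 4751 in KOd, and the pools differed from each other for 9721 genes in 2D and 7710 in 3D. Interactions with the largest positive log2 values were those of SAA2 (4.35), SAA1 (4.17), SAA2-SAA4 (4.17, a readthrough gene that shares reads with SAA2), SULT1B1 (4.10), TFPI2 (3.35), PLEKHA7 (3.35), CES1P2 (3.22) and MYH10 (3.17). The largest negative ones were those of TNFRSF19 (-5.05), CPE (-4.82), SEMA3A (-3.78), OLFML3 (-3.74), UNC5B (-3.60), CDH6 (-3.47), KRT17 (-3.42) and BMERB1 (-3.37). Among lists whose interaction passed with the preset correlation, of which ATF4 and amino acid response alone held with the estimated one (adjusted p = 0.032, against 0.081 to 0.60 for the others), the median was -0.68 for collagens, -0.29 for collagen processing and crosslinking enzymes, -0.83 for mesenchymal markers, -1.69 for basal keratins and myoepithelial markers, -0.80 for TGF-beta and SMAD targets, -0.35 for ERK feedback genes, -1.19 for ATF4 and amino acid response genes, -0.52 for p53 targets and -0.48 for ribosomal proteins. It was 0.36 for glycolysis, 0.71 for proliferation, 0.77 for the heat shock response and 1.36 for metallothioneins.

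For contrasts of 3 libraries with 3, the 10 splits of 6 libraries are too few for a share under 0.05. The real split gave 10398 genes for culture in wt, 10614 in labelled KOs and 10831 in KOd, 8681 and 7280 for labelled KOs and KOd against wt in 2D, 9190 and 5548 in 3D and 7710 between the pools in 3D, and the highest of the other splits was 0 in each with edgeR. Between the pools in 2D the real split gave 9721 and the highest other 26. For the remaining results the libraries were dealt anew to wt and the pools within each culture, in 60 splits with the real one. In each, 1 split, the real one, gave a result as large. This held too among the 28 that put wt 3D and KOd 3D libraries of the same letter in different groups. It is the smallest share these splits can give, and it argues against a random deal of these libraries. Whether other cultures would give such counts is not shown, since the labels do not state separate cultures. Real values and highest others were 7166 and 345 genes for the mean of the pools in 2D, 7823 and 4191 in 3D, 5099 and 1046 for its interaction, 6012 and 857 for that of labelled KOs, 4751 and 2703 for that of KOd, 2765 and 0 for genes changed in both pools in 2D, and 3689 and 2049 in 3D. Among the 28 the highest others in 3D were lower, with 77 for the mean of the pools, 0 for its interaction, 2 for that of KOd and 0 for genes changed in both pools.

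In 28 of 283 windows of 10 Mb, neighbouring genes were shifted together in labelled KOs against wt in 2D (23 lower, 5 higher), as on chromosome 13 from 20403669 to 50018467, where 91 genes had medians of -1.24 in 2D and -1.39 in 3D, with -0.33 and -0.93 in KOd and -0.16 for wt 3D against 2D. A smooth fit on GC content, gene length and expression left 90.8% of the median shift of the genes in the 28 windows, which argues against those trends as the whole cause. Thinning to the mean wt 2D total left 99.8%. Genes with a mean log2 CPM over 3 alone were counted in the windows, and thinning could hardly move their median. That value was therefore all but fixed beforehand and does not test depth or how the libraries were made. Copy number differing between the clones of the pools and wt may underlie the windows, of which 67.9% kept their sign with a size of at least 0.3 in 3D, but 7 of the 28 did so in the culture change of wt too, and without DNA, not analysed here, copy number and regulation cannot be told apart. At NNMT the level in labelled KOs stepped up by 0.98 in 2D and 1.03 in 3D between the 20 genes before and the 20 after, at percentile 99.3 by absolute size in both cultures among steps at 9274 genes (in KOd the steps were -0.19 and -0.18, at 69.0 and 86.6). The low side lay before NNMT: 49 genes up to 20 Mb before it had medians of -1.12 in 2D and -1.03 in 3D, and 79 genes after it 0.03 in both. Most windows of chromosome 11 from 10 to 110 Mb were low in labelled KOs 2D too. A chromosome break at the sgRNA site is a hypothesis from the same data and was not tested. In labelled KOs 68 and 67 genes had larger steps, and the largest on chromosome 11 lay at SIK3 in 2D and PTS in 3D.

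In 2D 66 genes in labelled KOs and 50 in KOd lay at least 32-fold below wt, with 40 shared against 0.26 for independent lists, and 34 of these were that low in both pools in 3D too, among them CADM1, BEX1, KLF8 and MEG3. CADM1 lies near NNMT on chromosome 11, from 115169236 to 115504415, and whether its low level is tied to that site was not tested. Of the 40, 11 were GAGE genes or unnamed IDs with the same reads as another in every library, and with such copies counted once 32 remained, several still from the GAGE locus, against 0.193 for independent lists. At the wt 2D level the pools would have held a median of 524 reads per gene and at least 87.4, a test void here because the genes were chosen at levels that ensure it. Other tested genes within 500 kb, 153 in number, had median log2 fold changes of -0.092 in labelled KOs and -0.089 in KOd. Neighbours nearly absent in both pools were left out of these medians, each of which spans all loci. The values argue against loss of a longer stretch for these neighbours as a set, but cannot exclude shorter losses or loss at single loci. Descent of both pools from the same minority of wt cells could give the 40 shared genes, and loss of NNMT could too, and the 2 cannot be told apart because no control pool without an NNMT sgRNA was sequenced.

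Labelled KOs 2D replicate A stood apart from replicates B and C, with r of 0.976 to 0.981 and a ribosomal RNA share of 2.70%, and no biological explanation was tested. In the chromosome 13 genes its median log2 difference from wt 2D was -1.36, which argues against a wt library under the wrong label. Admixture of tumorsphere cells of the same pool needs 1 share for all genes. Among 161 genes raised in labelled KOs 3D only 22.98% implied a share within a factor of 2 of the median of 1.65%, and 23 implied one below 0. The genes were taken from 10 CPM in labelled KOs 3D. At so small a share, noise between libraries in genes with few added reads can spread the values too, so this test does not decide on admixture. A difference in handling or in clones could not be tested.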

How the results depend on the processing

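The block in wt 3D and KOd 3D alone and leaving out the ribosomal RNA genes or the 3 libraries that stand apart were chosen after the data were seen, and the other alternatives before. No list call or named change that passed came to pass in the other direction. The NNMT changes in labelled KOs against wt, which did not pass, changed sign with 1 library left out, in 2D and in 3D. Which direction held more genes changed with the scaling in several counts, as given above. The 22 counts and correlations stayed within 1.5 times their count, or within their spread, with RLE factors, library totals alone, no filter, the strict filter, DESeq2, limma-voom, the compared groups alone and the replicate block, each where it was run. Without the ribosomal RNA genes the 18 counts of genes stayed within 1.5 times too, with 3018 positive and 2970 negative in the interaction of labelled KOs. With the replicate block in wt 3D and KOd 3D alone, 6012 genes passed for KOd against wt in 3D, 8193 for the mean of the pools in 3D, 5509 for its interaction, 5147 for that of KOd and 3873 in both pools in 3D, and of the list calls the ERK one for the interaction of KOd alone was lost (adjusted p = 0.055). Requiring an absolute log2 fold change of at least 1 keeps fewer genes by construction: 4677 for wt 3D against 2D, 4216 for labelled KOs 3D against 2D, 5061 for KOd 3D against 2D, 2745 for labelled KOs against wt in 2D, 2266 for KOd against wt in 2D, 3765 for labelled KOs against wt in 3D, 2113 for KOd against wt in 3D, 1803 for the mean of the pools in 2D, 2693 for the mean of the pools in 3D, 1817 for the interaction in the mean of the pools, 2716 in labelled KOs, 1800 in KOd, 3570 for KOd against labelled KOs in 2D, 2639 in 3D, 1643 for tumorsphere medium against 2D, 4979 for 3D against tumorsphere medium, 767 for both pools in 2D and 1423 for both pools in 3D. With adjusted p under 0.01, also fewer by construction, genes numbered 2826 for the interaction in the mean of the pools, 3798 in labelled KOs, 2822 in KOd, 3224 for tumorsphere medium against 2D, 1744 for both pools in 2D and 2444 for both pools in 3D. Without the 3 libraries that stand apart 7968 genes passed for tumorsphere medium against 2D, more than the 5224 with all libraries. None of the 3 is in this comparison, so they act on it only through what is fitted over all libraries, such as the shared spread. The compared groups alone, which leave them out too, gave 7706. Among genes with a mean of at least 10 CPM the culture changes correlated with r = 0.753 for wt and labelled KOs, 0.835 for wt and KOd and 0.742 for the pools, by construction with fewer genes of low counts.

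Leaving out 1 library at a time gave 9547 to 10145 for wt 3D against 2D, 9579 to 11534 for labelled KOs 3D against 2D, 9891 to 10444 for KOd 3D against 2D, 7641 to 9237 for labelled KOs against wt in 2D, 6213 to 6623 for KOd against wt in 2D, 8051 to 8605 for labelled KOs against wt in 3D, 4448 to 5370 for KOd against wt in 3D, 5737 to 8109 for the mean of the pools in 2D, 6958 to 7650 for the mean of the pools in 3D, 3949 to 6148 for the interaction in the mean of the pools, 5138 to 6893 in labelled KOs, 3898 to 4725 in KOd, 8858 to 10356 for KOd against labelled KOs in 2D, 6463 to 7188 in 3D, 2752 to 4531 for tumorsphere medium against 2D, 8418 to 10146 for 3D against tumorsphere medium, 2148 to 2807 for both pools in 2D and 3112 to 3498 for both pools in 3D. The lowest count for tumorsphere medium came without its replicate B, and without replicate A it was 3192; each leaves 1 library in that group, which was assumed to vary like the other groups. The correlations ran from 0.621 to 0.680 for wt and labelled KOs, 0.773 to 0.784 for wt and KOd, 0.679 to 0.719 for the pools and 0.176 to 0.284 for medium and culture format. Of 232 list calls, 10 held with the estimated correlation and 222 did not pass, 14 did not pass with fry, 13 with library totals alone, 3 with the replicate block and 1 with RLE factors, all in the same direction. Of 416 named values, 4 no longer passed with limma-voom and 8 of the values with 1 library left out, while 3 values with 1 library left out and 4 without the 3 libraries came to pass, and the cause was not tested. Those lost with 1 library left out were all of CHI3L1 and those gained all of NNMT. DESeq2 and the fit of the compared groups alone gave values for 395 and 411 of them. Scaling by library totals alone moved the median log2 fold change of all genes by 0.22 in labelled KOs 3D against 2D, by 0.16 and 0.16 for labelled KOs and KOd against wt in 3D, by 0.11 for KOd against wt in 2D, by 0.13 and 0.22 in the interactions of the mean of the pools and of labelled KOs, and by 0.15 between the pools in 2D. Depth limits the folds of genes with few reads in a group, such as COL1A2 with 2 to 9 per library in the tumorspheres of the pools.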

Other observations

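Lists outside the comparisons above are given here as values for the mean of the pools against wt, in which members that moved in 1 pool alone also count. In 2D the hypoxia response genes ERO1A (-1.04 ± 0.07) and KDM3A (-0.96 ± 0.11) fell and VEGFA rose (1.37 ± 0.13), and 16 of 26 of that list fell and 5 rose (18 and 5 over the list alone, camera adjusted p = 0.0036, 0.28 estimated). Caveolin CAV1 had -1.46 ± 0.15 and the integrin genes ITGB1 -0.75 ± 0.08 and ITGAV -0.72 ± 0.09, and 12 of 27 integrin and focal adhesion genes fell and 2 rose (13 and 2 over the list alone, camera adjusted p = 0.036, 0.39 estimated). In 3D CAV1 had -2.24 ± 0.15 and ITGAV -1.42 ± 0.09, and 14 of 27 of the same list fell and 4 rose (camera adjusted p = 0.031, 0.35 estimated). In 2D the luminal genes GATA3 (1.11 ± 0.14), KRT8 (0.67 ± 0.09) and CLDN4 (2.05 ± 0.51) rose, and 5 of 13 epithelial and luminal markers rose and 0 fell (camera adjusted p = 0.048, 0.28 estimated). The fatty acid uptake gene CD36 had 1.82 ± 0.39 in 2D, and 9 of 16 LXR and lipid efflux or storage genes rose and 0 fell there (camera adjusted p = 0.036, 0.31 estimated).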
